A study of Homo sapiens with 6 samples.

How the data were processed

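Gene expression was measured on single-colour Affymetrix arrays in 6 samples of 4175 cells, a variant of the human breast cancer line MDA-MB-231 selected for growth in the lung. Per the labels, 3 samples received an siRNA against PGC-1alpha, the protein of the gene PPARGC1A, and 3 received a control siRNA. Per the series design, the siRNA was given 24 hours after plating and acted for 48 hours. Per the labels' protocols, RNA was column-purified, and 10 ng of each sample was converted to sense-strand cDNA, fragmented and labelled with a low-input kit. Each sample was assigned to its group and replicate number by its title.

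The deposited values were read as log2 signals per probe set, 1 column per sample. The log2 scale was inferred from their range, since no label names it, and the base of the logarithm therefore rests on that reading. Background correction, summarisation and normalization by the authors are not given in the sources used here. Over the 17687 genes compared, the medians of the columns lay between 7.28 and 7.30. The standard deviation of 1 column over these genes, siPGC1alpha replicate 1, was 1.66 against 2.06 to 2.09 in the other 5. A further deposited table held 6 columns whose names match no sample, and these 6 columns were not used.

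The table held 24320 probe sets. A platform annotation table paired 17709 of them with 1 gene symbol, 0 with several and 6611 with none. All 17709 gene identifiers were found in the RefSeq table of assembly GRCh38.p14, which altered 0 symbols. Probe sets without a symbol comprised 63 ERCC spike-in, 612 negative control and 2197 positive control probe sets, 551 unmapped transcripts and 3188 others. For 20 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was kept, which left 17687 genes. No filter on dim genes was applied and no gene coordinates are given, because the build behind the array was not named. A detection call was not among the values used, so that signal above background could not be judged gene by gene. The number of arrays limits the precision.

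The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and plain eBayes) on the deposited log2 values of all 6 arrays, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are the siPGC1alpha mean minus the sicontrol mean. A total of 26 gene lists with 918 genes was drawn up, of which 797 genes were measured. The lists covered mitochondrial and metabolic programmes tied to PGC-1alpha, metastasis, matrix, adhesion, hypoxia, interferon, cytokines, proliferation, stress and ribosomes, and markers of cell types other than this line. The list of mitochondrially encoded genes had 0 measured members and was not tested. The other 25 lists were tested two-sided with limma's camera at a preset correlation between genes of 0.01, with adjustment over all lists. Camera with an estimated correlation and fry, a rotation test of whether the genes of a list move on balance in one direction without comparison with other genes, served as alternatives. The design, the lists, the rule for named genes and the settings listed below as planned were fixed before the data were examined.

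The rule for named genes took PPARGC1A, then in each direction the 10 genes with the largest change among those passing the threshold with non-overlapping groups. Where fewer passed, the genes with the smallest unadjusted p in that direction filled the 10, and genes known only by a locus or clone identifier were skipped. Up to 4 members of each list with the smallest unadjusted p were added. Genes named outside this rule are said to have been chosen after their values were seen.

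The settings varied were dim-gene filters at the 25th percentile and at the median of all genes, the mean of a gene's probe sets, quantile normalization, centring of each array on its median, eBayes with trend and robust options, the replicate number as a block, all probe sets that are not controls, an adjusted p under 0.1, and each array left out in turn, all planned. A comparison with the further deposited table was planned and was not run, because its columns could not be assigned to samples. Array weights and combinations of settings without siPGC1alpha replicate 1 were chosen after seeing the data, as was the decision to report the values without that array beside those of all 6 arrays. The test was tried on simulated data with the real means and spreads of the 17687 genes in 5 runs. With 5 arrays, 38.8% of genes changed by 0.5 on the log2 scale, 77.6% of those changed by 1 and 97.3% of those changed by 2 were called, with 26 false calls in total. With 6 arrays of which 1 carried the real deviation of siPGC1alpha replicate 1, 0% were called at each of these sizes. With 6 arrays that were all alike, 57.6%, 89.9% and 99.4% were called, with 31 false calls. A shift of 0.2 placed on the oxidative phosphorylation list was called by camera in 5 of 5 runs with 5 arrays, and 0 of 120 tests of unshifted lists were called. Genes were drawn independently of one another in these simulations. The list results therefore do not show how camera behaves where the genes of a list are correlated, as they may be on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.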

Results

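Transcript levels of 17687 genes were measured in 4175 cells, a lung-metastatic variant of the triple-negative breast cancer line MDA-MB-231. The 3 arrays labelled siPGC1alpha came from cells given an siRNA against PGC-1alpha, a transcriptional coactivator known for driving mitochondrial biogenesis and oxidative metabolism. The 3 arrays labelled sicontrol came from cells given a control siRNA. The question was which transcripts depend on PGC-1alpha in these cells after 48 hours. The titles number the replicates of each group from 1 to 3, but nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

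PPARGC1A, the gene the siRNA was directed against, was not lower on any array labelled siPGC1alpha than on the lowest control array. Its probe set (TC0400010242.hg.1) read 6.45, 6.49 and 6.49 on the control arrays (mean 6.48 ± 0.021, SD, n = 3). It read 7.95, 6.52 and 6.47 on siPGC1alpha replicates 1, 2 and 3. Replicates 2 and 3 averaged 6.50 ± 0.034 (SD, n = 2), a difference from the controls of 0.019 on the log2 scale (SE 0.071, 95% confidence interval -0.15 to 0.19, limma adjusted p = 0.9998). As a ratio this was 1.01, with an interval of 0.902 to 1.14. Over all 6 arrays the difference was 0.50 (SE 0.44, interval -0.57 to 1.57, limma adjusted p = 0.663), and it came from replicate 1. If the probe set reports the transcript, these values go against the label of a knockdown at the transcript level. No detection call settles whether it does. Its rise of 1.47 on replicate 1 was close to that of the ERCC spike-in probe sets, whose median rose by 1.42. Its control mean exceeded their control median of 5.08. The samples are called arrays labelled siPGC1alpha throughout. Whether this 1 probe set lies within the sequence the siRNA was directed against is not given in the sources used here.

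Genes whose products work with PGC-1alpha did not pass the test either. PPARG, the nuclear receptor for which PGC-1alpha was named, differed by 0.063 (SE 0.073) between replicates 2 and 3 and the controls. SIRT1, a deacetylase acting on PGC-1alpha, differed by 0.032 (SE 0.071), and ESRRB, an orphan nuclear receptor, by 0.045 (SE 0.091). On replicate 1 these genes lay -2.88, -2.01 and 1.86 from the control mean. Of the 18 measured members of the list of the PGC-1 family and its partner transcription factors, 0 passed over all genes and 0 when adjusted over the list alone, with or without replicate 1. The list's median difference was 0.052 over the 6 arrays, where camera pointed down (adjusted p = 0.544, and adjusted p = 0.570 with an estimated correlation), and 0.022 without replicate 1 (camera adjusted p = 0.771).

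**Figure D1:**
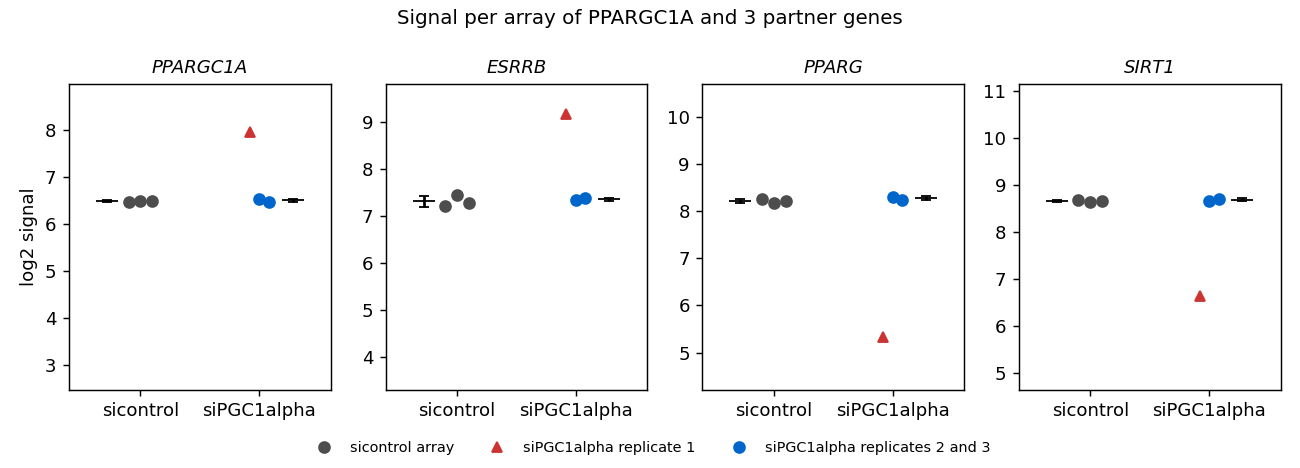
Log2 signal of PPARGC1A, ESRRB, PPARG and SIRT1 on each array, with sicontrol arrays in grey, siPGC1alpha replicate 1 as a red triangle and siPGC1alpha replicates 2 and 3 in blue; horizontal bars with whiskers show mean ± SD of the 3 control arrays and of siPGC1alpha replicates 2 and 3. PPARGC1A read 7.95 on replicate 1 and 6.52 and 6.47 on the other two, against a control mean of 6.48.

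The array of siPGC1alpha replicate 1 stood apart from the other 5 in nearly every gene group. Across genes, which are not independent replicates, it correlated with them at a Pearson r of 0.585 to 0.604, whereas the other 5 arrays correlated with one another at 0.995 to 0.996. Transcripts abundant in proliferating tumour cells read low on it. LDHA, lactate dehydrogenase A, was at 5.46 against a control mean of 12.86 ± 0.057 (SD, n = 3), and RPS24, a ribosomal protein, at 5.90 against 12.77 ± 0.076. The cytokine IL6 was at 3.85 against 11.45 ± 0.18, and the detoxifying enzyme MGST1 at 3.24 against 11.27 ± 0.060. LDHA and RPS24 fall under the rule for named genes, and IL6 and MGST1 were chosen after their values were seen. Of the 1769 genes in the brightest 10% on the control arrays, 88.6% were lower on this array than the control mean, with a median difference of -2.13. Genes in the dimmest 10% had a median difference of 1.10. On replicates 2 and 3 the brightest 10% had median differences of 0.011 and 0.023. ERCC spike-in probe sets, which no human transcript targets, had a median of 6.50 on replicate 1 against 5.08 ± 0.036 (SD, n = 3) on the control arrays.

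**Figure D2:**
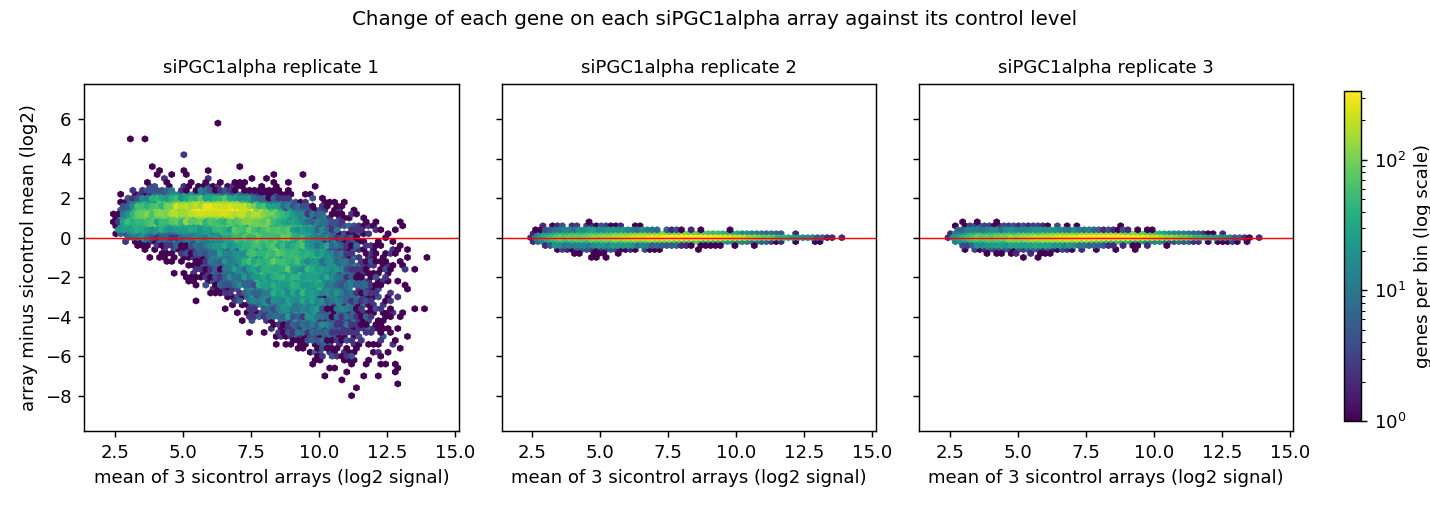
Difference of each gene on each array labelled siPGC1alpha from the mean of the 3 sicontrol arrays (log2, vertical axis) against that mean (log2 signal, horizontal axis), with the number of genes per bin coloured on a log scale and a red line at 0. On replicate 1 the brightest 10% of genes had a median difference of -2.13 and the dimmest 10% had 1.10, while on replicates 2 and 3 the brightest 10% had 0.011 and 0.023.

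No gene passed the test between the arrays labelled siPGC1alpha and the controls. The genes with the smallest unadjusted p among those higher included AMHR2, the receptor of anti-Müllerian hormone, with a difference of 0.84 (SE 0.30) over 6 arrays and 0.59 (SE 0.13) without replicate 1. CCL11, the chemokine eotaxin, had 1.11 (SE 0.45) and 0.65 (SE 0.19), DOCK8, an activator of small GTPases, 0.82 (SE 0.34) and 0.48 (SE 0.086), and GPER1, a membrane estrogen receptor, 0.49 (SE 0.21) and 0.42 (SE 0.077). Among those lower were MEF2C, a transcription factor that PGC-1alpha coactivates in muscle, with -0.72 (SE 0.27) and -0.57 (SE 0.16), and ADAM12, a metalloprotease of the cell surface, with -0.62 (SE 0.33) and -0.32 (SE 0.11). ULBP2, a ligand of the natural killer cell receptor NKG2D, had -0.77 (SE 0.43) and -0.54 (SE 0.36), and the zinc finger gene ZFP69 -0.39 (SE 0.22) and -0.48 (SE 0.072). ULBP2 read 8.46 on sicontrol 1 against 9.73 and 9.63 on the other controls, and without sicontrol 1 it differed by -1.18. Control means of AMHR2, CCL11, DOCK8 and MEF2C were 4.44, 5.08, 4.96 and 4.19, near or below the ERCC spike-in median of 5.08 and above the negative control median of 3.36. Those of GPER1, ADAM12, ULBP2 and ZFP69 were 5.67, 7.16, 9.27 and 5.33.

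The other genes taken by the rule were TREH, OR10H5, ZNF660, SLC17A2, CCDC89 and OR4A16 on the higher side, with differences of 0.64, 0.52, 0.48, 0.73, 0.89 and 0.85 over 6 arrays. On the lower side they were ERICH2, DEPDC4, ANAPC15, DCLK1, ZNF708 and PAPPA2, with -0.94, -0.49, -0.63, -0.54, -0.66 and -0.46. None of these 20 genes passed the test (lowest limma adjusted p = 0.663). TREH encodes trehalase, OR10H5 and OR4A16 encode olfactory receptors, and ANAPC15 a subunit of the anaphase-promoting complex. Without replicate 1 the differences on the higher side were, in the same order, 0.46, 0.49, 0.46, 0.45, 0.51 and 0.46 (SE 0.093 to 0.19). On the lower side they were -0.56, -0.40, -0.31, -0.29, -0.30 and -0.33 (SE 0.11 to 0.22). Control means of OR4A16, CCDC89 and SLC17A2 were 3.10, 3.48 and 3.51, near or below the negative control median of 3.36, so their differences lie at the level of background. Those of the other genes in this paragraph ranged from 4.28 (TREH) to 9.30 (ANAPC15).

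By limma, 0 genes were higher and 0 lower over the 6 arrays, with 3 genes at an unadjusted p under 0.05 where 884 would be so by chance. In simulated arrays with the deviation of replicate 1, 0% of genes changed by 2 on the log2 scale were called. The count over the 6 arrays therefore cannot show that no gene changed. Without siPGC1alpha replicate 1 the count was again 0 and 0, with 786 genes at an unadjusted p under 0.05, of which 373 were higher and 413 lower (lowest limma adjusted p = 0.9998). With gene-by-gene array weights, chosen after seeing the data, the count was 0 with 1417 genes at an unadjusted p under 0.05, and with array weights fitted by REML, which did not converge, it was 1639. Groups did not overlap for 1287 genes over 6 arrays (7.28%, where chance gives 10%) and for 3484 without replicate 1 (19.7%, where chance gives 20%). The median half-width of the 95% interval was 0.99 on the log2 scale with replicate 1 and 0.22 without it. Without it, the interval excluded a 2-fold difference in either direction for 17670 genes (99.9%).

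Genes of mitochondrial energy metabolism, the programme best known to depend on PGC-1alpha, differed little between replicates 2 and 3 and the controls. The 69 measured nuclear-coded genes of oxidative phosphorylation had a median difference of 0.011, with 38 above 0 and 31 below. ATP5F1D, a subunit of ATP synthase, differed by -0.15 (SE 0.094), and NDUFV2, a subunit of complex I, by -0.11 (SE 0.075). The 74 genes of the mitochondrial ribosome had a median of 0.035 with 54 above 0, among them MRPL10 at 0.18 (SE 0.078). Medians were 0.028 for 21 genes of mitochondrial DNA maintenance and expression, including SSBP1 (-0.15, SE 0.10) and TFB2M (-0.054, SE 0.085), and 0.017 for 28 genes of the TCA cycle and pyruvate entry, including CS (-0.016, SE 0.076) and PDP1 (-0.12, SE 0.078). The 33 genes of fatty acid oxidation had a median of 0.050, with ACADS at 0.26 (SE 0.11) and the carnitine carrier SLC25A20 at 0.24 (SE 0.088). The 31 genes of reactive oxygen defence had a median of 0.0053, with SESN2 at 0.20 (SE 0.089).

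With all 6 arrays the same mitochondrial lists had medians of -0.72 for oxidative phosphorylation, -0.57 for the mitochondrial ribosome, -0.57 for mitochondrial DNA maintenance, -0.42 for the TCA cycle, -0.16 for fatty acid oxidation and -0.56 for reactive oxygen defence. All 6 lists passed camera as lower at the preset correlation, and each had adjusted p = 0.314 with an estimated correlation. On replicate 1 alone the oxidative phosphorylation genes lay at a median of -2.06 from the control mean, and on replicates 2 and 3 at 0.016 and 0.00085. On that same array the leukocyte and endothelial markers lay at 1.27, the luminal and epithelial markers at 1.20 and the ERCC spike-in probe sets at 1.42. Without replicate 1, 0 of these lists passed camera, and 0 members passed over all genes or when adjusted over the list alone.

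Genes of glycolysis and biosynthesis lay below the controls over the 6 arrays and close to them without replicate 1. Over the 6 arrays the lists of glycolysis and of glutamine, serine and folate metabolism passed camera as lower at the preset correlation, and each had adjusted p = 0.314 with an estimated correlation. The 23 genes of glycolysis and lactate transport had a median of -0.38 over 6 arrays and of 0.030 without replicate 1, where LDHA differed by -0.073 (SE 0.080), GAPDH by -0.032 (SE 0.076) and ALDOC by 0.21 (SE 0.089). Glutamine, serine and folate metabolism (21 genes) had -0.71 and 0.040, with ASNS, asparagine synthetase, at -0.079 (SE 0.12) in the latter. Cholesterol synthesis and uptake (19 genes) had -0.12 and 0.035, and fatty acid and triglyceride synthesis (25 genes) had -0.050 and 0.035, neither past the threshold. SREBF2, a regulator of cholesterol synthesis, differed by 0.16 (SE 0.074) without replicate 1.

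Genes tied to metastasis, matrix and the response to low oxygen or to transfected RNA also lay close to the controls once replicate 1 was left out. The 24 genes of the lung metastasis signature, which was derived by others from lung-seeking variants of MDA-MB-231, had a median of -0.078 over 6 arrays and 0.0087 without that array. The chemokine receptor CXCR4 differed by 0.32 (SE 0.14) and MAN1A1 by 0.20 (SE 0.12) in the latter. Epithelial-mesenchymal transition and matrix (41 genes) had -0.20 and -0.0027, and camera pointed up in the latter against the sign of the median. MMP3, a matrix metalloproteinase, differed by 0.35 (SE 0.18), and the transcription factor ZEB1 by -0.099 (SE 0.070). Integrins and adhesion (28 genes) had -0.17 and -0.017, and hypoxia and angiogenesis (27 genes) had -0.27 and 0.038, with FGF2 at 0.28 (SE 0.14) and HIF1A at -0.095 (SE 0.084). Interferon-stimulated genes (39) had 0.075, with camera pointing down, and 0.036, with TRIM22 at 0.29 (SE 0.087) and IFIT3 at -0.072 (SE 0.073). The control mean of TRIM22 was 3.52, near the negative control median of 3.36, and that of IFIT3 was 9.46. Inflammatory cytokines and NF-kappaB targets (25 genes) had -0.15 and 0.028, with CCL5 at 0.11 (SE 0.11) and IL1B at 0.043 (SE 0.070). Of these 6 lists, integrins and hypoxia passed camera as lower over the 6 arrays, each with adjusted p = 0.314 with an estimated correlation.

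Proliferation, stress and ribosome lists lay below the controls over the 6 arrays and close to them without replicate 1. The 47 genes of the G2 and M phases had a median of -1.10 over 6 arrays (camera adjusted p = 1.45e-12, and adjusted p = 0.314 with an estimated correlation) and of 0.020 without replicate 1 (camera adjusted p = 0.617), with the spindle checkpoint kinase BUB1B at -0.086 (SE 0.079) and the kinesin KIF2C at -0.065 (SE 0.083). DNA replication and S phase (44 genes) had -0.45 and 0.030, with CCNE1, cyclin E1, at -0.11 (SE 0.083). The unfolded protein and ATF4 stress response (33 genes) had -0.18 and 0.0044, with ATF3 at 0.11 (SE 0.091). Apoptosis and p53 targets (27 genes) had -0.032 and 0.027, with MDM2, which restrains p53, at -0.15 (SE 0.093). Lysosome and autophagy (32 genes) had -0.25 and 0.0056, with ATG5 at -0.050 (SE 0.097). Cytosolic ribosomal proteins (43 genes) had -0.90 and 0.010, with RPS24 at -0.026 (SE 0.080). All 6 lists passed camera as lower over the 6 arrays, and all had adjusted p = 0.314 with an estimated correlation.

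Markers of other cell types were included to look for foreign cells. Luminal and epithelial markers (22 genes), which this mesenchymal line expresses weakly, had a median of 0.39 over 6 arrays and were the only list past camera's threshold as higher (adjusted p = 0.039, and adjusted p = 0.554 with an estimated correlation). Without replicate 1 the median was 0.00069 with camera pointing down (adjusted p = 0.840), and GRHL2, an epithelial transcription factor, differed by 0.27 (SE 0.099). Leukocyte and endothelial markers (21 genes) had 0.31 (camera adjusted p = 0.074) and -0.026 (camera adjusted p = 0.501), with ITGAM at -0.015 (SE 0.10) and the endothelial claudin CLDN5 at 0.090 (SE 0.10) in the latter.

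Over the 6 arrays, 17 of the 25 lists passed limma's camera at the preset correlation, 16 as lower and 1 as higher, and 0 passed with an estimated correlation or with fry (lowest adjusted p = 0.314 and 0.612). Without replicate 1, 0 lists passed camera (lowest adjusted p = 0.501), and 1 list, the mitochondrial ribosome, had an unadjusted p under 0.05. With an estimated correlation and with fry the count without replicate 1 was also 0 (lowest adjusted p = 0.742 and 0.404). In both fits 0 members of any list passed over all genes and 0 when adjusted over the list alone. The 1 probe set of PPARGC1A showed no lower signal, and whether it reports the transcript stays open. A lower PPARGC1A transcript was thus not shown, and no direction given here can be attributed to one.

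**Figure D3:**
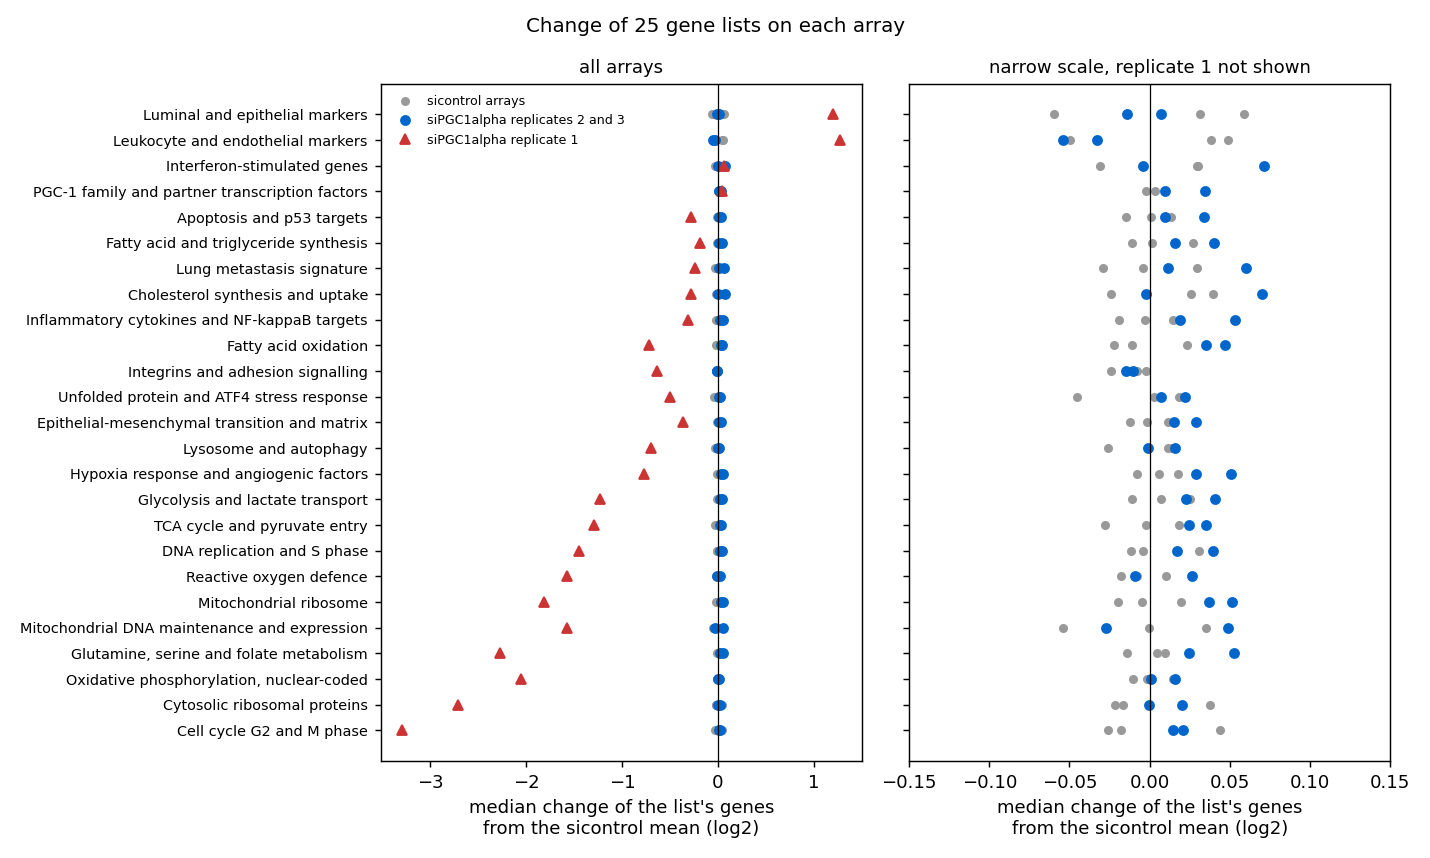
Median difference of the genes of each of 25 lists from the mean of the 3 sicontrol arrays (log2, horizontal axis) on each array, with sicontrol arrays in grey, siPGC1alpha replicates 2 and 3 in blue and siPGC1alpha replicate 1 as red triangles; the right panel has a narrower axis and leaves replicate 1 out. The G2 and M phase list lay at -3.29 on replicate 1 and at 0.015 and 0.021 on replicates 2 and 3.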

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

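The tests on siPGC1alpha replicate 1 and on exchanged labels were chosen only after their results were seen, and those on the PPARGC1A probe set and on other splits of the arrays were chosen before.

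Of the 5 classes of probe sets outside the gene comparison, 4 had a higher median on siPGC1alpha replicate 1 than on every control array. The median of the 63 ERCC spike-in probe sets was 6.50 there, against at most 5.11 on a control array. The median of the 612 negative control probe sets was 3.79 against at most 3.44. The median of the 3188 probe sets without a gene name was 7.01 against at most 6.50. The median of the 551 unmapped transcripts was 7.09 against at most 6.62. The 2197 positive control probe sets were the exception, with a median of 8.41 there against 10.39 to 10.43 on the control arrays.

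Replicate 1 of the arrays labelled siPGC1alpha stood apart from the other 5 arrays. A mere difference in scale or normalization would leave the ranks of genes alike, but the lowest Spearman rho with another array was 0.547. Intact RNA of another human sample would keep ribosomal protein genes bright, but their median change was -2.71, and an siRNA effect shared by its group would recur on replicates 2 and 3, but the slope of their changes on those of replicate 1 was -0.019. Loss of target RNA signal on that array, as from little or degraded RNA, needs abundant transcripts to read lower and non-human probe sets to read higher, and the brightest 10% of genes changed by a median of -2.13 while all ERCC probe sets (100%) lay above every control array. The array may thus carry a failed amplification or hybridisation, a hypothesis found and tested on the same values, while an effect of the siRNA in that sample alone stays open and untested. The ribosomal protein genes bear only on intact RNA, so little or degraded RNA of another sample also stays open.

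PPARGC1A was not lower on the arrays labelled siPGC1alpha. The array carried 1 probe set of the gene and no detection call was at hand, so whether it reports the transcript stays open. For the same reason an exchange of labels between groups among the 5 alike arrays stays open, although PPARGC1A spanned 0.067 on the log2 scale over these 5 arrays and no regrouping of them could give a larger difference. A knockdown that did not take hold, that had passed by the time of sampling, or that acts on the protein may also apply. Among the 5 alike arrays, those labelled siPGC1alpha shared no common change of many genes. Against separate control arrays their changes correlated across genes at a median of -0.00066 (range -0.12 to 0.10). A broad effect through the protein was thus not seen there, while an effect on a few genes or below the noise stays open. No protein and no other time were measured, so the values cannot tell whether a knockdown failed or had passed.

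Over the 6 arrays, 17 lists passed camera and 0 genes passed limma, with 3 genes at an unadjusted p under 0.05. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes and the highest other split 0 (10 of 10 splits gave as many). With a real count of 0 every split has to give as many, so the count of genes decides nothing here. The real split gave 17 lists and the highest other split 20 (9 of 10 splits gave as many), which points to a structure of the samples, the array of replicate 1, that lies on 1 side of each split.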

How the results depend on the processing

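Array weights and all settings combined with leaving out siPGC1alpha replicate 1 were chosen only after the result was seen, and the others were planned. The count of genes stayed at 0 under limma in every planned setting and with each array left out (range 0 to 0), with 0 to 8 genes at an unadjusted p under 0.05 under the planned settings other than leaving out an array. All planned settings but the one without siPGC1alpha replicate 1 kept that array. With its deviation, the simulated main fit called 0% of genes changed by 2 on the log2 scale. A count of 0 that includes it is therefore no evidence that genes were unchanged. The count of genes became 1639 with REML array weights, which gave siPGC1alpha replicate 2 a weight of 33.6 and replicates 1 and 3 weights of 0.011 and 0.30. That estimate did not converge, and 5 of the 9 other splits gave as many genes under it (0 to 3762). Gene-by-gene weights gave 0 genes (lowest adjusted p = 0.0856, against 0.00138 with REML weights and 0.439 to 0.9999 without weights). Without siPGC1alpha replicate 1 it also stayed at 0 with trend and robust options, the filter at the median and all probe sets, with 732, 366 and 946 at an unadjusted p under 0.05. The difference of PPARGC1A stayed above 0 and not significant, at 0.019 to 0.76 with each array left out and 0.50 to 0.54 under the other planned settings, and was 0.041 and 0.016 with REML and gene-by-gene weights. The filter at the median removed PPARGC1A, so it has no value there.

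The 17 lists past the threshold became 0 with an estimated correlation, 0 with fry, 6 with the dim filter at the median, 0 with either kind of array weights, and 0 to 20 with each array left out, the 0 being without siPGC1alpha replicate 1. Without that array they also stayed at 0 with trend and robust options, with the dim filter at the median, with an estimated correlation and with fry. The filter at the 25th percentile, the mean of probe sets, quantile normalization, median centring, trend and robust options, and the replicate block gave 12 to 19. The threshold of 0.1 and all probe sets were planned and run for the count of genes only. Fewer genes were tested under the filters. On siPGC1alpha replicate 1 the brightest 10% of genes had a median change of -2.13 and the dimmest 10% of 1.10. Camera sets a list against the other genes, so lists of bright genes read lower beside dim genes on that array. The filters take out dim genes. How much of the counts this explains was not tested, nor was any other cause.

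List medians or test directions turned under a few settings. The PGC-1 family list was at 0.012 and -0.0023 with the filters at the 25th percentile and the median, 0.15 after quantile normalization and 0.052 with fry. Cholesterol synthesis was at 0.14 and 0.18 with the same filters, and interferon-stimulated genes at 0.042 with the filter at the median and 0.075 with fry. After quantile normalization the medians of the lung metastasis and cytokine lists turned to 0.0077 and 0.020, while camera still pointed down. The cause was not tested.

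With each array left out, the test direction of 24 of the 25 lists turned, always without siPGC1alpha replicate 1. Their medians ranged from 0.022 to 0.051 for the PGC-1 family, -0.84 to 0.028 for mitochondrial DNA maintenance, -1.09 to 0.011 for oxidative phosphorylation, -0.89 to 0.035 for the mitochondrial ribosome, -0.64 to 0.017 for the TCA cycle, -0.37 to 0.050 for fatty acid oxidation, -0.82 to 0.0053 for reactive oxygen defence and -0.60 to 0.030 for glycolysis. They ranged from -1.10 to 0.040 for glutamine, serine and folate, -0.21 to 0.035 for cholesterol, -0.084 to 0.035 for fatty acid synthesis, -0.42 to 0.038 for hypoxia, -0.18 to 0.0087 for lung metastasis, -0.36 to -0.0027 for epithelial-mesenchymal transition, 0.034 to 0.084 for interferon and -0.25 to 0.028 for cytokines. They ranged from -1.68 to 0.020 for G2 and M phase, -0.70 to 0.030 for S phase, -0.24 to 0.0044 for the stress response, -0.063 to 0.027 for apoptosis, -0.37 to 0.0056 for lysosome, -1.36 to 0.010 for cytosolic ribosomes, 0.00069 to 0.59 for luminal markers and -0.026 to 0.57 for leukocyte markers. Integrins kept their direction, at -0.29 to -0.017.

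The 20 named genes kept their direction in every setting that kept them, and 16 of them passed under REML array weights. The lower dim-gene filter kept only GPER1, ADAM12, ANAPC15, DCLK1, ULBP2 and ZNF708 of these genes. The filter at the median kept only ANAPC15 and ULBP2. All were picked for a small unadjusted p on these same arrays, so a kept direction is no independent check. With the replicate number as a block, 0 genes and 19 lists passed and PPARGC1A differed by 0.50. Deviations of arrays of the same number from their group means correlated at -0.25, -0.18 and -0.086. It was not the case that every control array correlated best with its own number. The mean of the siPGC1alpha group includes the deviating replicate 1, so these correlations cannot tell whether arrays of the same number share a culture or day. Leaving an array out keeps 2 arrays in its group, and no detection call shows which genes lay above background.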

Other observations

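The tests of genes that read higher on siPGC1alpha replicate 1 and of other splits of the 5 arrays were chosen only after the result was seen, and that of a change shared by siPGC1alpha replicates 2 and 3 was chosen before.

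A small number of genes read far higher on siPGC1alpha replicate 1, against the lower signal of abundant transcripts there. Only 17 genes lay more than 3 above the control mean on the log2 scale, and 1295 lay more than 3 below it. GRAMD1B, a sterol transporter, was at 12.07 against 6.31 ± 0.14 (SD, n = 3) on the control arrays. RETREG1, a receptor for autophagy of the endoplasmic reticulum, was at 8.02 against 3.01 ± 0.22. CP, ceruloplasmin, was at 8.62 against 3.68 ± 0.36, and NPNT, the matrix protein nephronectin, at 9.33 against 5.12 ± 0.10. TSPAN7 was at 9.26 against 5.11 ± 0.30, PRKAR2B, a regulatory subunit of protein kinase A, at 10.68 against 7.04 ± 0.14, and the cadherin CDH6 at 7.69 against 4.20 ± 0.20. On replicates 2 and 3 these genes averaged 6.25, 2.98, 4.0, 5.0, 5.17, 7.22 and 4.21. They were chosen after their values were seen, and 1 array gives no measure of their spread. The bound taken for loss of target RNA was the largest rise of the 675 ERCC and negative control probe sets, which was 4.45. The prediction was that no gene would exceed it. With 17687 genes set against 675 probe sets, some genes could pass this bound without any target, so the prediction is too strict. The genes that exceeded it were 3, GRAMD1B, RETREG1 and CP. The other 4 genes named here lay within it. The largest rise came from a negative control probe set. No ERCC probe set rose by more than 1.99, and all 17 genes above exceeded that. The answer depends on which bound is taken, so these genes decide neither for nor against such a loss.

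PPM1L, a protein phosphatase, had the smallest unadjusted p without replicate 1 and was chosen after its values were seen. It read 4.02, 4.12 and 4.01 on the control arrays and 3.37 and 3.38 on siPGC1alpha replicates 2 and 3, a difference of -0.67 (SE 0.075, limma adjusted p = 0.9998). On siPGC1alpha replicate 1 it read 4.62.

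Replicates 2 and 3 were set against the controls to ask whether they share a change, as an siRNA effect common to both would give. Across genes, which are not independent replicates, their changes from the mean of the same 3 controls correlated at 0.270, where 100 simulations of unchanged arrays against those controls gave a mean of 0.251 and at most 0.278. Their covariance was 0.00617, within the simulated 0.00550 to 0.00695 (mean 0.00620, difference -2.87e-05). Against separate control arrays, the median correlation over 6 pairings was -0.00066 (range -0.12 to 0.10). A common change of many genes was thus not seen, which leaves changes of a few genes or below the noise open.

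In the 10 splits of the 5 arrays other than siPGC1alpha replicate 1 into 3 and 2, 0 genes and 0 lists passed limma and camera. The real split had 786 genes at an unadjusted p under 0.05, and the other 9 had 687 to 1579. The highest count set sicontrol 1 and siPGC1alpha 3 against the rest, and the next, 1426, set sicontrol 2 and sicontrol 3 against the rest. How far such counts spread with no difference between arrays was not simulated.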
